A study of Mus musculus with 6 samples.

How the data were processed

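Total RNA of mouse embryonic stem cells from 6 groups (control, Chd4 or Mbd3 shRNA at day 0 or day 4), in 1 sample per group, was labelled and hybridized to Mouse Gene 2.0 ST arrays, which read transcripts with probe sets along the whole gene. Per the series design text, the authors analysed the arrays in GeneSpring GX 12.6.1. RMA, which subtracts background, makes the distributions of the arrays equal by quantiles and summarizes probes into probe sets, is named without a version in the submitters' processing notes. The deposited values are intensities on a linear scale: they ran from 17.4 to 7980, and the array medians from 39.6 to 41.4. Each array's lowest intensity was above 17, which an added constant of 16 would give; no source used here states one. Such a constant would shrink folds of dim genes, so 16 was subtracted before log2 in an alternative. The genome build behind the probe sets is not given in the sources used here, and no coordinates are printed.

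Log2 of the deposited intensities was taken with no further scaling. Of 34351 probe sets, 23521 carried 1 gene symbol in the platform's annotation, 1814 carried several and 9016 carried none; genes were named from the first kind only, and symbols were updated through the RefSeq table of assembly GRCm38.p6, which held the gene ID of 23328 of them. This gave 22180 genes, of which 1082 had more than 1 probe set; a gene was represented by its probe set with the highest mean over the 6 arrays. Samples were grouped by the labels. Of the 589 symbols in the gene lists, 525 matched exactly, 11 matched through a synonym, and 53 were not analysed here; neither was the p53 gene itself, which stands in none of the lists.

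With 1 array per group, a difference between 2 arrays has no test. For each such comparison a gene entered where the brighter of the arrays reached that array's median over all probe sets, and genes past 2-fold (a log2 difference of 1 or more in size) were counted. For the 28 gene lists, the median log2 difference was set among 10000 random lists of the same size, drawn from 20 bins of mean expression; a percentile of at most 2.5 or at least 97.5 was called outside the random range, as a description of these arrays. The lists covered NuRD subunits, p53 targets, apoptosis machinery, core and naive pluripotency, primed epiblast, early neural progenitors, postmitotic neurons, other embryonic and extraembryonic lineages, germline and two-cell-stage genes, fibroblasts, cell cycle, stress, interferon and signaling responses, metabolism, histones and housekeeping genes. Some genes stand in more than 1 list.

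limma 3.58.1 in R 4.3.3 fitted an additive model of shRNA and day to the 12926 genes whose mean reached the median over all probe sets, with 2 residual degrees of freedom, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The sources used here do not say whether a sample is 1 culture or a pool, or whether cultures were repeated. The p-values thus cannot be taken to measure the spread between cultures. They set the shared effect of day or shRNA against the departure of 6 arrays from additive effects, which counts as error. An effect that differs between lines or days therefore makes these p-values larger. camera tested the lists with a preset correlation of 0.01 and with an estimated correlation. Correlations between effects were computed across genes for 9 pairs of comparisons. Where both shared a control array, 100 simulations of unchanged arrays, with the spread of the difference between the knockdowns, gave a value for comparison. Other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

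On simulated data with 200 changed genes among 12926 and the residual spread of the real fit, the additive fit recovered 69% of genes changed by 1 on the log2 scale between days and 28% of those changed by 1 in the Chd4 contrast, and 100% and 97% of those changed by 2, with 20 and 2 false calls. Another setting gave every gene the same spread, that of the difference between the knockdowns at day 0, whereas the spread of the real fit varies between genes. There the fit recovered 97% and 86% of genes changed by 1, with 1 and 11 false calls. Of those changed by 2 it recovered 100% in both. The fit of 2 knockdown arrays against 1 control array at day 4 recovered 71% and 100%, with 11 false calls. Each simulated change was of equal size in all changed arrays and fell on randomly drawn genes. In the data, genes that change can do so by unequal amounts between lines or days, which counts as error in the additive fit. The recovered shares therefore do not carry over to the real counts. Of 100 random lists of 30 genes without a shift, 6% fell outside the random range in the comparison of Chd4 with control at day 0. Those lists were drawn at random, so this cannot show how often a list of coexpressed genes falls outside. Of the 28 gene lists, 5 lay above and 4 below the range in that comparison, and 1 and 10 for Mbd3 at day 0. At day 4 these counts were 9 and 7 for Chd4, and 7 and 6 for Mbd3. Between the days in control they were 6 and 9.

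The comparisons, the lists and the rule for naming genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest genes of each comparison, leaving out predicted and RIKEN clone genes, microRNA, snoRNA, olfactory and vomeronasal receptor genes and a class of ribosomal RNA entries, up to 4 members of each list by size of difference, and the NuRD, p53 and pluripotency members. Genes named for the direct comparison of both knockdowns, for overlaps and in the closing section were chosen after their values were seen. Alternatives were median centring, cyclic loess, no filter on dim genes or a stricter one at the 75th percentile, the mean of a gene's probe sets, a limma variance trend with robust fitting, leaving out arrays, list means, unmatched random lists and list members past the filter only. Added after seeing the data were the subtraction of 16, the fit of both knockdowns against control within each day, and a floor: every intensity under 41.4, the highest of the 6 array medians, was set to it, and a named gene with 1 of its 2 intensities under the floor is given as "at least" its difference from the floor. The array median is not a measured background.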

Results

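Gene expression was measured in mouse embryonic stem cells that had been infected with a lentivirus carrying a short hairpin RNA (shRNA) against Chd4, against Mbd3, or a control shRNA. Chd4 encodes the ATPase, and Mbd3 a methyl-CpG-binding domain protein, of the nucleosome remodeling and deacetylase complex (NuRD), which removes acetyl groups from histones and moves nucleosomes. Each of the 3 lines was sampled as stem cells in medium with leukemia inhibitory factor (LIF), called day 0, and after 4 days of neural differentiation as floating aggregates, called day 4. The 6 resulting groups hold 1 Mouse Gene 2.0 ST array each, so that no difference between 2 arrays has a replicate check, and the number of arrays limits the precision. The median intensity over all probe sets ranged from 39.6 to 41.4 between the arrays. Values below are differences of log2 intensities or folds between 2 arrays, and "higher" and "lower" describe these arrays. No detection call is used here. Where the dimmer intensity of a named gene lay under 41.4, the highest array median, its difference is given against 41.4 as "at least", a bound without a rank; this floor was chosen after seeing the data.

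The targeted genes came first, as a check of the labels. The Chd4 probe set had an intensity of 973 in control cells and 290 in Chd4-knockdown cells at day 0, which is 29.8% of control. At day 4 it stood at 1021 in control and 727 in the Chd4 knockdown, or 71.3% of control. The Mbd3 probe set was at 43.0% of control in Mbd3-knockdown cells at day 0 and at 75.5% at day 4. Each knockdown thus left its target closer to the control level at day 4 than at day 0, and in the Chd4 line the Chd4 intensity was 2.51-fold higher at day 4 than at day 0. Chd4 stayed at 92.1% and 92.3% of control in the Mbd3 knockdown, and Mbd3 at 94.7% and 112% of control in the Chd4 knockdown, at day 0 and day 4. Of the 16 NuRD subunits and paralogs measured, Chd3, a paralog of Chd4, differed by at least 2-fold in the Chd4 knockdown besides Chd4 itself, with a log2 difference of 1.32 at day 0 and -1.49 at day 4.

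**Figure D1:**
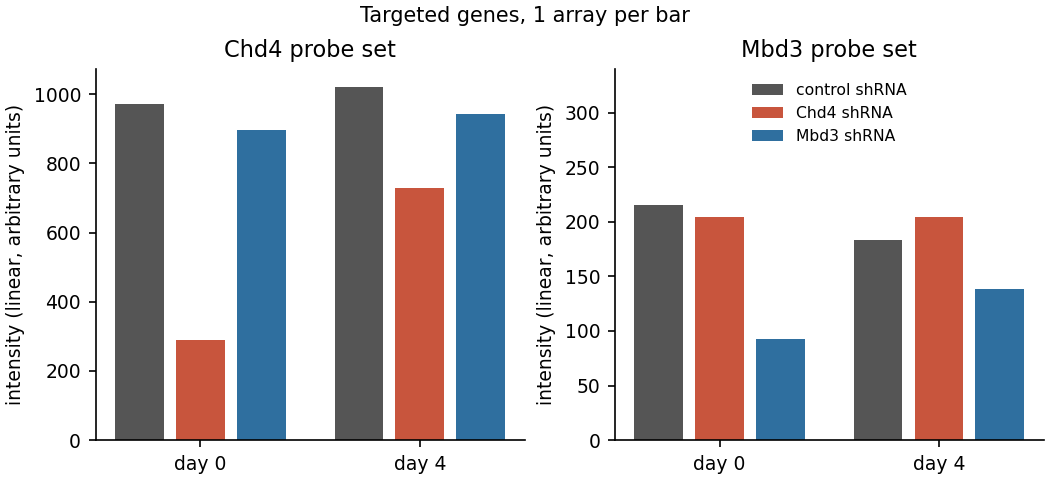
Linear intensity of the Chd4 (left) and Mbd3 (right) probe sets in the 6 arrays, 1 array per bar, by day on the horizontal axis and shRNA by color. Chd4 in the Chd4 knockdown is at 29.8% of control at day 0 and 71.3% at day 4, and Mbd3 in the Mbd3 knockdown at 43.0% and 75.5%.

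Day 4 was set against day 0 in control cells to see what the differentiation protocol itself changed. Genes of the early neural tube were far higher at day 4: Fabp7, a fatty-acid-binding protein of radial glia, by at least 29.4-fold, Sox1, a transcription factor of the neural plate, by 22.2-fold, and the homeobox gene Meis2 by 21.3-fold. The retinoic-acid-binding proteins Crabp2 and Crabp1 were 19.5-fold and 17.7-fold higher, and Lrrn1, Meis1 and Ednrb were 18.2-fold to 20.8-fold higher, with Ptn at least 16.3-fold and Ndnf at least 15.9-fold higher. Genes of naive stem cells were lower, among them Tfcp2l1 by 10.6-fold, Tcl1 by 9.23-fold, Nr0b1 by 9.07-fold and Tbx3 by 7.99-fold. Bmp4, a signal that holds back neural fate, was 11.2-fold lower, and Bcl3, a target of LIF signaling, 7.79-fold lower. Hsd17b14, Morc1, Dppa2 and Dnmt3l completed the 10 lowest genes.

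Of 13831 genes compared in control cells, 1125 were at least 2-fold higher and 650 at least 2-fold lower at day 4. Of 32 early neural progenitor genes, 24 were at least 2-fold higher and 0 lower, with a median log2 difference of 2.04. Of 25 genes of postmitotic neurons, 18 were at least 2-fold higher, among them the bHLH factors Nhlh1 and Neurod4, with log2 differences of at least 2.68 and 2.28. Of 24 naive pluripotency genes, 21 were at least 2-fold lower (list median -1.77), and of 19 core pluripotency genes 10 were (list median -1.31), including Nanog at -1.59 and Pou5f1 at -1.31. In the core list, Lin28b was 1.81 and Lin28a 0.21 higher on the log2 scale. The medians of 16 cholesterol synthesis genes (0.82) and 20 primed epiblast genes (0.61) lay above the 97.5th percentile of 10000 random lists matched on size and mean expression, and those of 11 LIF and STAT3 response genes (-1.17), 7 Nodal response genes (-1.23) and 38 p53 target genes (-0.43) lay below the 2.5th percentile.

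The same step in the knockdown lines gave fewer large differences. In the Chd4 knockdown 228 genes were at least 2-fold higher and 155 lower at day 4, and in the Mbd3 knockdown 213 and 147. With 16 subtracted from each intensity, 641 and 640 genes in place of 383 and 360 passed 2-fold. The control total stayed within 1.5 times of its value. Fabp7 was higher by at least 1.10 on the log2 scale in the Chd4 knockdown and at least 1.74 in the Mbd3 knockdown, against at least 4.88 in control, and Sox1 by at least 1.94 and at least 3.12, against 4.47 in control. The early neural progenitor median was 0.16 and 0.23 in the Chd4 and Mbd3 knockdowns, with 4 and 6 of the 32 genes at least 2-fold higher; with values under 41.4 set to it these medians were 0 and 0.12, against 1.90 in control. The naive pluripotency median was -0.40 and -0.65, and the core pluripotency median -0.10 and -0.15. The LIF and STAT3 response median was -0.68 in the Chd4 and -0.49 in the Mbd3 knockdown, against -1.17 in control; its member Bcl3 was lower at day 4 in all 3 lines, with log2 differences of -2.96 in control, -2.59 in the Chd4 knockdown and -2.29 in the Mbd3 knockdown. The primed epiblast median was 0.52 and 0.81 in the knockdowns, on both sides of the control value.

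**Figure D2:**
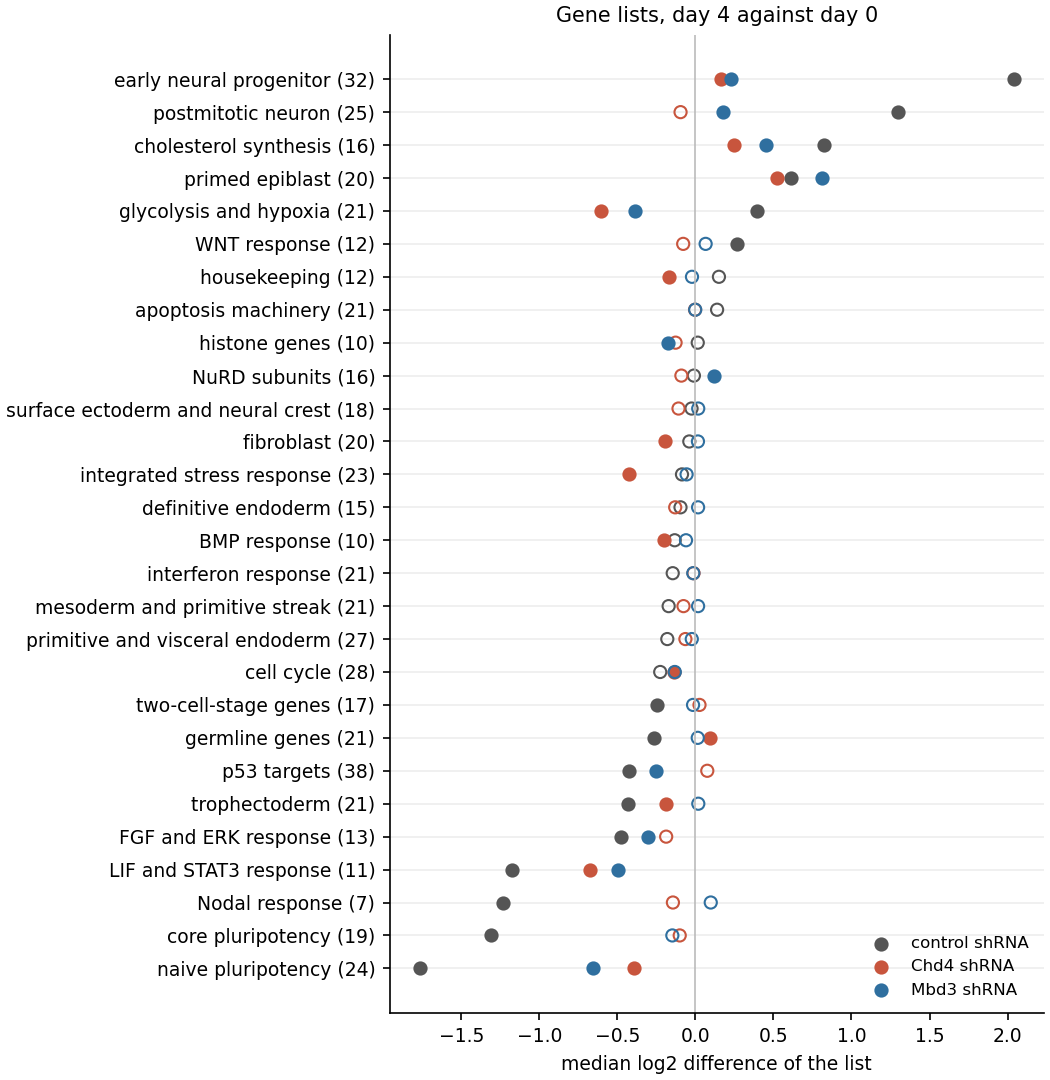
Median log2 difference between day 4 and day 0 for 28 gene lists (number of genes in parentheses) in control, Chd4-knockdown and Mbd3-knockdown cells, 1 array per group and day; filled points lie outside the 2.5th to 97.5th percentile of matched random lists. The early neural progenitor median is 2.04 in control against 0.16 and 0.23 in the knockdowns, and the glycolysis and hypoxia median is 0.39 in control against -0.60 and -0.39.

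Genes that differed between the days in control cells were then followed in the knockdown arrays, which share no array with the control pair. The 1125 genes at least 2-fold higher at day 4 in control had a median log2 difference of 1.45 there, 0.16 in the Chd4 knockdown and 0.39 in the Mbd3 knockdown. Of these genes, 67.2% were higher at day 4 in the Chd4 knockdown and 87.9% in the Mbd3 knockdown, against 48.0% and 46.4% of all genes compared. The 650 genes lower in control had medians of -1.45 in control, -0.20 in the Chd4 knockdown and -0.45 in the Mbd3 knockdown. Across 12926 genes, which are not independent replicates, the day difference of control correlated with that of the Chd4 knockdown at r = 0.25 and with that of the Mbd3 knockdown at r = 0.55, and the knockdowns correlated with each other at r = 0.56.

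**Figure D3:**
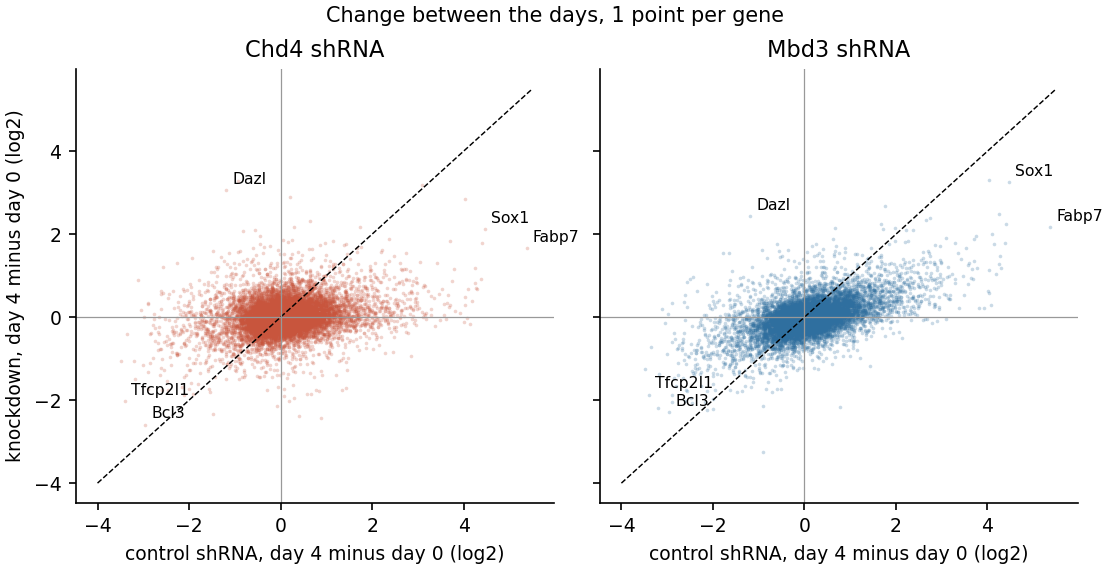
Log2 difference between day 4 and day 0 in the Chd4 knockdown (left) and Mbd3 knockdown (right) against that in control cells, 1 point per gene for the 13831 genes compared in control; the dashed line marks equal differences. Points are spread wider along the control axis, and Bcl3 lies near the line while Fabp7, plotted at its measured 5.38 in control, lies at 1.66 and 2.17 in the knockdowns.

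Over the 3 lines together, limma with an additive model of shRNA and day called 0 of 12926 genes between the days at an adjusted p under 0.05, with 1962 genes at an unadjusted p under 0.05. A day difference that varies between the lines counts as error in this model, so 0 calls do not show that nothing changed. Bcl3 was not called, with log2 differences of -2.96 in control, -2.59 in the Chd4 and -2.29 in the Mbd3 knockdown. Without the control pair limma called 683 genes between the days in the knockdown lines. That fit takes the Chd4 and Mbd3 lines, different knockdowns, as replicates of each other and has still fewer residual degrees of freedom. The early neural progenitor list had a median of 1.03 in this fit; camera gave an adjusted p = 2.17e-08 with a preset correlation of 0.01 and an adjusted p = 0.68 with an estimated correlation. None of the 28 lists passed with an estimated correlation in any of the 4 contrasts of this model. With an estimated correlation camera has only the 2 residual degrees of freedom of the fit, so it could hardly detect a shift. It gave the definitive endoderm list, with a median of -0.14, the same adjusted p = 0.68 between the days. That no list passed therefore does not show that the lists did not move. Adjusted over the list alone, 7 of 24 early neural progenitor genes, 9 of 19 primed epiblast genes, 8 of 23 naive pluripotency genes and 6 of 10 LIF and STAT3 genes passed, with 0 in each list over all genes tested.

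The effect of Chd4 knockdown in stem cells was taken from day 0. Cyclin D2, encoded by Ccnd2, was 6.33-fold lower than in control, and cyclin D1, encoded by Ccnd1, 3.17-fold lower; both drive the G1 phase of the cell cycle. Next to Chd4, at 3.36-fold lower, stood Zscan4e, a gene of the 2-cell-like state, at 3.44-fold lower, and the replication gene Pold2 and the cytoskeletal gene Septin2 at 3.25-fold and 3.24-fold lower. Pramel19, Fgf17 and Trim36 were 2.91-fold to 3.26-fold lower and Cbr3 at least 2.88-fold. The highest genes were the noncoding transcript Ptprtos (5.63-fold), the RNA export factor gene Nxf3 (at least 3.27-fold), the ATP-gated channel gene P2rx7 (3.73-fold), Retreg1 (3.24-fold) and the proteoglycan gene Bgn (3.17-fold). Elovl4, Actn2, St8sia6, Acss1 and Gpnmb were 3.01-fold to 3.07-fold higher.

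In all, 93 genes were at least 2-fold higher and 76 lower among 13446 compared. The medians of early neural progenitor genes (-0.13, with 28 of 32 genes lower) and core pluripotency genes (-0.20) lay below the 2.5th percentile of matched random lists and that of naive pluripotency genes (0.19) above the 97.5th, with 0 of 32, 1 of 19 and 1 of 24 genes past 2-fold. With values under 41.4 set to it, 13 of the 32 early neural genes showed no difference and that median was -0.0002. The single core gene was Foxd3, at -1.14, and the single naive gene was lower too. The p53 target median was -0.03, at percentile 39.2 of matched random lists, with 18 of 38 genes higher and Cd80, at 1.27, the largest difference; Mdm2, which encodes the ligase that degrades p53, differed by -0.02. The integrated stress response list had the largest positive median, 0.33, above the 97.5th percentile, with 17 of 23 genes higher and Nupr1, Chac1 and Atf4 at 1.38, 0.88 and 0.67. The FGF and ERK response list had a median of -0.39, below the 2.5th percentile, with Spry4 at -1.30 and Etv4 at -0.78. With 16 subtracted from each intensity before log2, an alternative chosen after seeing the data, 324 genes in place of 169 passed 2-fold.

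Mbd3 knockdown in stem cells also left Ccnd2 lowest, at 5.06-fold below control. Myc was 3.21-fold lower and the growth factor gene Fgf15 3.04-fold lower, followed by Ceacam1, the neurofilament gene Nefl, Foxd3, Trim36, Plet1, Usp17le and Vgll3 at 2.48-fold to 3.02-fold lower. The receptor gene Adgrg6 was 3.62-fold higher, the ATP-gated channel gene P2rx4 2.79-fold and the large scaffold gene Ahnak2 2.76-fold higher. Kif21a, Tmem150a, Dnm1, Copz2, Got1l1, Slc38a3 and Vcan were 2.37-fold to 2.66-fold higher.

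Among 13389 genes compared, 49 were at least 2-fold higher and 42 lower. The p53 target median was 0.30, above the 97.5th percentile of matched random lists, with 30 of 38 genes higher but 0 of them by 2-fold. Trp53cor1 was at 0.89, Trp53inp1 and Ptprv at 0.86, Apaf1 at 0.79, Perp at 0.60 and Mdm2 at 0.53. The medians of cholesterol synthesis genes (-0.31), core pluripotency genes (-0.25), primed epiblast genes (-0.24) and early neural progenitor genes (-0.20) lay below the 2.5th percentile; the last was -0.002 with values under 41.4 set to it. With 16 subtracted from each intensity, 206 genes in place of 91 passed 2-fold.

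At day 4, Chd4-knockdown cells differed from control at 697 genes higher and 912 lower by at least 2-fold, among 13733 compared. Among the 10 lowest genes, Ednrb was 14.9-fold, Fabp7 13.7-fold and Meis1 13.3-fold lower, and the homeobox genes Dbx1 and Hoxb2 at least 17.2-fold and at least 12.3-fold. Ccnd2 was again among the lowest, at 15.7-fold, with Ildr2, Zfhx4 and the WNT antagonist gene Sfrp1 between 12.1-fold and 14.5-fold lower and Frzb, also a WNT antagonist gene, at least 9.83-fold. Higher were Dazl, an RNA-binding protein of germ cells, by 22.3-fold, Morc1 by 15.8-fold and Ptprtos by 13.4-fold. Cpn1, Aqp3, Efhc2 and Zfp936 were 9.11-fold to 11.6-fold higher, and Cyp2b23, Slc5a4b and the immune ligand gene Cd80 at least 9.92-fold, 9.51-fold and 7.94-fold.

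Of the 32 early neural progenitor genes, 22 were at least 2-fold lower than in control and 0 higher (list median -2.12), including Ptn at -3.08, Irx3 at -3.01 and Hes5, lower by at least 2.92. Of 25 postmitotic neuron genes 18 were at least 2-fold lower (median -1.54). All 24 naive pluripotency genes were higher, 17 of them by 2-fold (median 1.82), with Tbx3 at 2.36 and Zfp42 at 2.04, and of 19 core genes 8 were at least 2-fold higher and 1 lower (median 0.97), with Dppa4 at 2.46, Nanog at 1.00, Pou5f1 at 0.97 and Lin28b at -1.60. Of 38 p53 targets, 33 were higher, 9 of them by 2-fold (median 0.62): Cd80 was higher by at least 2.99, Epha2 stood at 1.77, Plk2 at 1.43, Perp at 1.39 and Mdm2 at 0.87. Of 21 germline genes, 10 were at least 2-fold higher (median 0.88), with Sohlh2 at 2.47 and Stra8 higher by at least 2.35; Tdrkh, lower by at least 1.97, was the 1 gene lower by that size. With values under 41.4 set to it the germline median was 0.27, with 9 of 21 genes at least 2-fold higher. Of 7 Nodal response genes 5 were at least 2-fold higher (median 1.45). Of 21 glycolysis and hypoxia genes 7 were at least 2-fold lower and 1, Pfkp at 1.25, higher (median -0.66), with Egln3 at -2.64, Bnip3 at -2.23 and Vegfa at -2.09, and 4 of 16 cholesterol synthesis genes were at least 2-fold lower (median -0.83). Each of these medians lay outside the 2.5th to 97.5th percentile of matched random lists.

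In Mbd3-knockdown cells at day 4, 468 genes were at least 2-fold higher and 665 lower than in control, among 13588 compared. Dbx1 was 14.5-fold, Hoxb2 10.9-fold and Ccnd2 10.3-fold lower, Zfhx4, Ednrb, Ildr2, Meis1 and Frzb were 8.88-fold to 10.5-fold lower, and the nicotinic receptor gene Chrna3 and Prdm8 at least 10.3-fold and 8.52-fold. Higher were Morc1 (7.91-fold), the zinc-finger genes Zfp936 (7.43-fold) and Zfp981 (7.41-fold), and Dnmt3l, a cofactor of DNA methylation (7.26-fold). Lrrc15, Dazl, Bnc2 and Zfp640 were 6.04-fold to 7.11-fold higher, and Cd80 and Cyp2b23 at least 7.22-fold and 4.01-fold.

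Of the 32 early neural progenitor genes 22 were at least 2-fold lower (median -1.61), as were 18 of 25 postmitotic neuron genes (median -1.34). All 24 naive pluripotency genes were higher, 14 by 2-fold (median 1.07), and of 19 core genes 5 were at least 2-fold higher and 1, Lin28b at -1.08, lower (median 0.83). Of 38 p53 targets 32 were higher, 6 by 2-fold (median 0.54), with Cd80 higher by at least 2.85, Perp at 1.84, Epha2 at 1.58, Trp53inp1 at 1.27 and Mdm2 at 0.99. The Nodal response median was 1.34, the glycolysis and hypoxia median -0.75 and the cholesterol synthesis median -0.77. The germline median was 0.16, with 3 of 21 genes at least 2-fold higher and 1, Tdrkh, lower, and the median was 0 with values under 41.4 set to it. Of the NuRD genes, Mta3 stood at 1.15 and Chd3 at -1.16. With 16 subtracted from each intensity, 1710 genes in place of 1133 passed 2-fold.

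**Figure D4:**
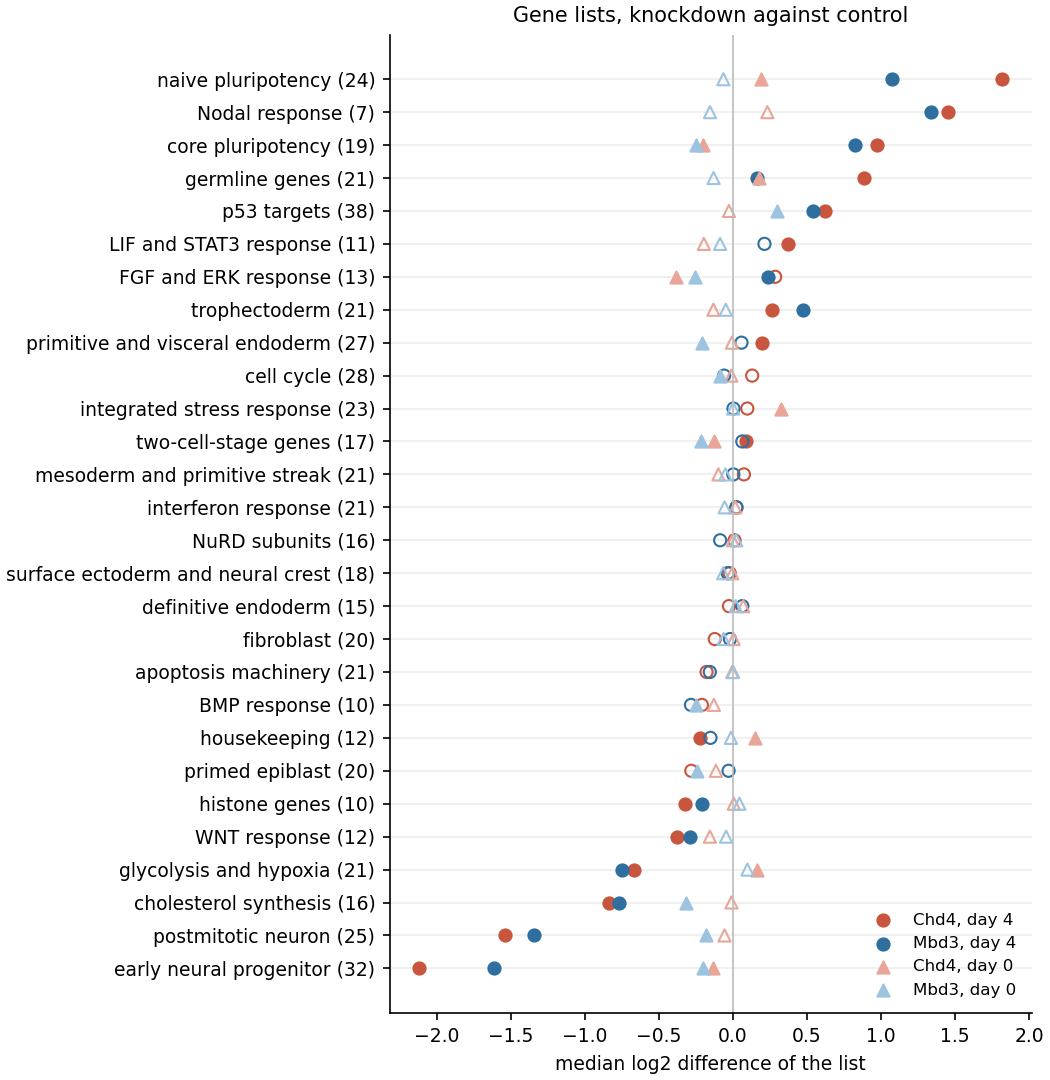
Median log2 difference between knockdown and control for 28 gene lists (number of genes in parentheses) at day 0 (triangles) and day 4 (circles), 1 array per group; filled symbols lie outside the 2.5th to 97.5th percentile of matched random lists. At day 4 the early neural progenitor median is -2.12 and -1.61 and the naive pluripotency median 1.82 and 1.07 in the Chd4 and Mbd3 knockdowns, while at day 0 these medians lie between -0.20 and 0.19.

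The effects of the knockdowns were compared with each other and between days. At day 4, 380 genes were at least 2-fold higher and 613 lower in both knockdowns, against 22.0 and 45.2 for independent lists. The effects correlated across genes at r = 0.92 with a covariance of 0.36, where unchanged groups against a shared control array gave r = 0.50 and a covariance of 0.04 in simulation. At day 0, 8 genes were higher in both (Adgrg1, Ampd3, Copz2, Dnm1, Lrrc31, P2rx4, Phf19 and Tek) and 19 lower, including Ccnd1, Ccnd2, Myc, Fgf15 and Fgf17, against 0.293 and 0.242 for independent lists. The day 0 effects correlated at r = 0.47 with a covariance of 0.04, where the simulation gave r = 0.50 and a covariance of 0.05. The simulated spread, equal for all arrays, came from the difference between the knockdowns and so holds any real difference between them. The day 0 correlation was thus no larger than in the simulation, which cannot show how much of it the shared control array gives. An equal spread in all arrays gives r = 0.50 by construction, at day 4 as well. A control array that departed further than the knockdown arrays would raise r without any knockdown effect, which was not simulated. With 1 control array per day the controls could not be split, and part of either overlap or correlation may come from the shared array. Between days, where no array is shared, the effects correlated at r = 0.05 for Chd4 and r = 0.10 for Mbd3. In all 4 comparisons Ccnd1, Ccnd2, Fgf15, Nefl and Soga3 were at least 2-fold lower and Ampd3, Phf19 and Tek at least 2-fold higher.

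Set directly against each other, the knockdowns differed by at least 2-fold at 78 genes higher and 62 lower in Chd4 than in Mbd3 at day 0, and at 123 higher and 24 lower at day 4. With 16 subtracted from each intensity, 295 and 266 genes in place of 140 and 147 passed 2-fold. The filter at the 75th percentile left 94 at day 4. Ptprtos led at both days, with log2 differences of 2.64 and 3.07, and Bgn stood at 1.76 and 2.12. At day 4 Fthl17b, Cpn1 and Ddr2 were higher in the Chd4 knockdown by 2.52, 2.47 and at least 2.21, and Nrk and Igf2 were lower, at -1.97 and -1.53. The germline median was 0.54 at day 4, with 19 of 21 genes higher in the Chd4 knockdown (0.14, with 14 higher, where values under 41.4 were set to it).

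Over both days, limma with the additive model called 0 of 12926 genes for Chd4 against control, Mbd3 against control and Chd4 against Mbd3. A knockdown effect that differs between the days counts as error in this model, so 0 calls do not show an absence of effect. At an unadjusted p under 0.05 limma gave 1014, 647 and 358 genes. Without the day 0 control array it called 2566, 2085 and 18 genes, and without the day 4 control array 4, 1 and 18. In these 2 fits the control array that is left is fitted exactly and assumed to vary like the knockdown arrays, which alone give the spread, so that the counts against control include any departure of that 1 array. The lists with the smallest adjusted p were early neural progenitor genes in the Chd4 fit, with a median of -1.25 (adjusted p = 1.77e-09 by camera with the preset correlation, adjusted p = 0.78 with an estimated correlation) and p53 targets in the Mbd3 fit, with a median of 0.42 (adjusted p = 1.39e-09, and adjusted p = 0.73 with an estimated correlation).

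A fit chosen after seeing the data set the Chd4 and Mbd3 arrays of a day, taken as 2 replicates of a NuRD knockdown, against the single control array of that day, which is assumed to vary like the knockdown arrays. The spread comes from the knockdown arrays alone, so that these p-values cannot separate an effect of the knockdowns from a departure of the 1 control array. At day 4 this fit called 546 genes higher and 1003 lower at an adjusted p under 0.05, including 21 of 24 early neural progenitor genes lower, 14 of 23 naive pluripotency genes higher, 9 of 19 glycolysis and hypoxia genes lower and 5 of 37 p53 targets higher. Fabp7 was at -3.46 ± 0.28 (SE, adjusted p = 0.0050) and Tbx3 at 2.37 ± 0.17 (SE, adjusted p = 0.0049). At day 0 it called 0 genes, with 815 at an unadjusted p under 0.05; Ccnd2 there was at -2.50 ± 0.29 (SE, adjusted p = 0.74).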

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

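The tests of explanations below, the fit that pools both knockdowns and the floor at 41.4 were chosen after the results were seen. In the limma fit that pools both knockdowns, the difference from control at day 4 differed from that at day 0 for 337 of 12926 genes at an adjusted p under 0.05, 110 with a higher and 227 with a lower value at day 4, among them Myc by 2.16 ± 0.30 (SE, adjusted p = 0.037). Each day has 1 control array and the spread comes from the knockdown arrays alone, so this count includes any departure of a single control array and does not by itself show that the effect of the knockdowns changed.

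Some gene lists lay outside the random range in opposite directions in 2 of the comparisons; these differences were not tested. Core pluripotency genes were lower in both knockdowns at day 0 and higher at day 4, with a difference of medians of 1.17 for Chd4 and 1.08 for Mbd3. Two-cell-stage genes did the same in the Chd4 knockdown, by 0.22, and FGF and ERK response genes in the Mbd3 knockdown, by 0.49. With values under 41.4 set to it, the two-cell-stage medians of both days were 0. Glycolysis and hypoxia genes were higher in the Chd4 knockdown at day 0 and lower at day 4, by -0.83, and housekeeping genes likewise, by -0.37. Between day 0 and day 4 the germline median was lower in control and higher in the Chd4 knockdown, a difference of 0.36; both medians were 0 with values under 41.4 set to it. The glycolysis and hypoxia median was higher at day 4 in control and lower in both knockdowns, a difference of -0.997 for Chd4 and -0.78 for Mbd3. Among 9016 probe sets without a gene symbol, which enter no comparison, 4 at day 0 and 114 at day 4 were at least 2-fold higher in both knockdowns than in control.

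The first pattern is the day 4 gap, with neural genes lower and pluripotency genes higher in both knockdowns than in control. Scaling of an array keeps the order of its genes, but the early neural progenitor genes fell in rank within the array by a median of 21.8 percent of all genes from control to the Chd4 knockdown and 17.1 to the Mbd3 knockdown (-21.8 and -17.1, with SDs of 1.37 and 1.22 for matched random lists), while naive pluripotency genes rose by 16.4 and 14.2 and core genes by 4.38 and 3.98. A faulty control array at day 4 would leave genes picked from it without direction elsewhere. Of the genes at least 2-fold higher in control, 87.9% were also higher at day 4 in the Mbd3 knockdown, against 46.4% of all genes. In the Chd4 knockdown 67.2% were, against 48.0% of all genes. These values argue against a faulty array as the whole cause, by a smaller margin in the Chd4 line. A candidate explanation is slower progress along the path that control cells took: of 135 genes past 2-fold in the same direction in both knockdowns between the days, 114, or 84.4%, moved that way in control, against 49.8% of all genes compared. The other 21 moved the opposite way, among them Dazl, at 3.06 and 2.44 in the Chd4 and Mbd3 knockdowns and -1.19 in control, and Cyp2b23, at 3.29 and 1.61 and lower by at least 0.23 in control. Slower progress gives no such genes where each gene moves in 1 direction along the path. With only day 0 and day 4 sampled, it cannot be told whether such genes reverse along the control path. Some of the 21 also moved little in control, such as Slc38a3 at 0.20. How much of the gap slower progress accounts for is therefore not settled. The medium changed with the day in all lines, so that a shared response to the medium stays open for the agreement of the 135 genes. A response equal in all lines would not give the gap itself. For the gap, a difference between single samples stays open too.

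The second pattern is the higher p53 target list at day 4. A rise of these genes in knockdown cells during differentiation would put the list above the 97.5th percentile between the days in both knockdowns, but it lay at the 90.7th percentile in the Chd4 knockdown and below the 2.5th in the Mbd3 knockdown. For the Chd4 knockdown, whose median at day 0 was -0.03, a drop of the same genes in control cells is consistent with the control median of -0.43, below the 2.5th percentile, although this test shares the day 4 control array with the pattern. For the Mbd3 knockdown such a drop is argued against as the whole cause, because the list was already above control at day 0, with a median of 0.30 and 30 of 38 genes higher, against 0.54 at day 4. p53 activity itself was not measured, and several genes of the list, such as Epha2 and Perp, may respond to other regulators as well.

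The third pattern is the lower glycolysis and hypoxia list in both knockdowns at day 4. Slower progress along a path on which the list rises steadily would move it upward by less. Its median between the days was instead -0.60 in the Chd4 knockdown, where control stood at 0.39. That argues against slower progress along such a path only. With only day 0 and day 4 sampled, an early drop of the list in control cannot be excluded. Array scaling is argued against by the rank of these genes within the array, which fell by a median of 6.24 percent of all genes in the Chd4 and 6.31 in the Mbd3 knockdown (-6.24 and -6.31, with SDs of 0.79 and 0.68 for matched random lists). The size of the aggregates could set their oxygen level; no measurement of it was used here, so this stays open and untested.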

How the results depend on the processing

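The subtraction of 16 and the floor at 41.4 were chosen after the results were seen. In the 9 comparisons of 2 arrays, counts past 2-fold stayed within 1.5 times of the reported value under median centring, cyclic loess, no filter, the mean of probe sets, the floor and the filter at the 75th percentile, except that this filter left 94 genes for Chd4 against Mbd3 at day 4, having fewer to compare. With 16 subtracted before log2 the counts were 324 (Chd4, day 0), 206 (Mbd3, day 0), 1710 (Mbd3, day 4), 641 and 640 (day 4 against day 0 in Chd4 and Mbd3), and 295 and 266 (Chd4 against Mbd3, day 0 and day 4); the subtraction itself enlarges folds of dim genes. The additive limma counts of 0 stayed at 0 under median centring, cyclic loess, no filter, the mean of probe sets, the variance trend and the subtraction. For the days, a fit without the shRNA as a replicate block called 19 genes, and leaving out a line called 0 to 683 (683 without the control pair). Leaving out an array called 0 to 2566 genes for Chd4, 0 to 2085 for Mbd3 and 0 to 18 for Chd4 against Mbd3; the highest came without the day 0 control array, and without the day 4 control array the counts were 4, 1 and 18. In both, the lone control array is assumed to vary like the knockdown arrays, which alone give the spread.

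All 10 splits of the 6 arrays into 3 and 3 gave 0 called genes (real split 0, highest other 0), and 10 splits are too few for a share under 0.05.

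Over the 9 comparisons and the day 4 minus day 0 difference of each knockdown effect, 139 list medians lay outside the random range. Of their 973 values under alternatives, 2 changed sign (WNT response, below) and 16 were 0, all with values under 41.4 set to it; these were germline, two-cell-stage and other lists with many dim members. Early neural progenitor medians were -1.67 (mean of probe sets), -1.75 (mean of members), -2.38 (16 subtracted), -2.27 (bright members) and -1.91 (floor) for Chd4 at day 4, -1.44, -1.49, -1.72 and -1.72 for Mbd3 at day 4, and 1.64, 1.88, 2.38, 2.21 and 1.90 for control between days. Naive pluripotency was 1.66 (mean of probe sets) for Chd4 at day 4, 1.30 (mean of members) and 1.24 (16 subtracted) for Mbd3 at day 4, and -1.98 and -1.97 for control between days. Core pluripotency was 0.73 (mean of members) for Mbd3 at day 4, and -1.16 (mean of members) and -1.52 (16 subtracted) for control between days. The p53 target median of Mbd3 at day 0 was 0.38 with 16 subtracted. The WNT response median between days in control turned from 0.26 to -0.014 as a mean, with Bmp4 at -3.49 among its members, and that of the Mbd3 effect at day 4 minus day 0 from -0.34 to 0.010. Unmatched random lists changed none of the 13 calls tried. Of 500 values, under alternatives, of the genes named from 5 comparisons (each knockdown against control at each day, and control between days), 464 moved by less than 1 SD of their comparison and 36 by more, 29 of them with 16 subtracted. Dim genes are limited by the lowest intensities, near 17, and single arrays limit all values.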

Other observations

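The RNA classes, gene families and single genes in this part were chosen after their values were seen, and no test is given for them. The gene lists at its end were fixed before the data were examined. Protein-coding genes had a median of -0.03 in the Chd4 knockdown against control at day 4, and -0.05 in the Mbd3 knockdown. Between the days, 124 of 13190 protein-coding genes were at least 2-fold lower at day 4 in the Chd4 knockdown (median -0.01). In the Mbd3 knockdown 142 were (median -0.03), and in control 611 (median -0.003). Of 45 box C/D snoRNA genes, 17 were at least 2-fold lower at day 4 than at day 0 in the Chd4 knockdown (median -0.71), against 0 in the Mbd3 knockdown (median -0.28) and 0 in control (median -0.02). Against control, their median in the Chd4 knockdown was 0.20 at day 0 and -0.55 at day 4. Of 25 box H/ACA snoRNA genes, 4 were lower by that size in the Chd4 knockdown (median -0.31), 1 in the Mbd3 knockdown (median -0.06) and 0 in control (median 0.05). Of 18 microRNA genes of the Mir297, Mir466, Mir467 and Mir669 families, 12 were at least 2-fold higher than control in the Chd4 knockdown at day 4 and 14 in the Mbd3 knockdown, with medians of 1.40 and 1.65; at day 0 the medians were 0.21 and 0.89. Sfmbt2, the gene that hosts many of them, was 2.49 higher than control in the Chd4 and 2.57 in the Mbd3 knockdown at day 4, and at -0.13 and 0.73 at day 0. Probes of such repeated sequences cannot be assigned to single copies.

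At day 4 the 10 Pramel genes had a median of 1.08 against control in the Chd4 knockdown and 0.23 in the Mbd3 knockdown, the 4 Fthl17 genes 1.75 and 0.14, and the 6 Rhox genes 0.88 and 0.61. Smc1b, a cohesin subunit of meiosis, was 1.42 higher in the Chd4 than in the Mbd3 knockdown, and Piwil2, of the piRNA pathway, 1.23 higher. The thioredoxin-interacting protein gene Txnip and its relative Arrdc4 were lower at day 4 than at day 0 in all 3 lines, at -3.26 and -2.14 in the Mbd3 knockdown, -1.50 and -1.02 in the Chd4 knockdown and both at -0.91 in control. Septin2 and Pold2 were both at -1.70 against control in the Chd4 knockdown at day 0, and at -0.43 and -0.38 at day 4; in the Mbd3 knockdown they were at -0.19 and -0.64 at day 0 and at -0.33 and -0.37 at day 4. The shRNA sequences were not used here.

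Other lists at day 4 had these medians in the Chd4 and Mbd3 knockdowns against control: trophectoderm 0.27 and 0.48, LIF and STAT3 response 0.37 and 0.21, FGF and ERK response 0.29 and 0.24, primitive and visceral endoderm 0.20 and 0.06, cell cycle 0.13 and -0.06, integrated stress response 0.10 and 0.00, two-cell-stage genes 0.09 and 0.06, mesoderm 0.08 and 0.00, interferon response 0.03 and 0.02, NuRD subunits 0.01 and -0.08, surface ectoderm and neural crest -0.02 and -0.03, definitive endoderm -0.03 and 0.06, fibroblast -0.12 and -0.02, apoptosis machinery -0.18 and -0.15, BMP response -0.21 and -0.28, housekeeping -0.22 and -0.15, primed epiblast -0.28 and -0.03, histone genes -0.32 and -0.20, and WNT response -0.38 and -0.29.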
